A study of Homo sapiens with 36 samples.

How the data were processed

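Messenger RNA was sequenced from 36 frozen cell pellets. There were 6 pure cell cultures and 6 mixtures of them made in vitro, each with 3 replicate pellets. The pure groups were the breast cancer lines BT474, T47D and MCF7, the monocytic leukemia line Thp1, the T-cell leukemia line Jurkat and human mesenchymal stem cells, written hMSC. Groups and replicate names were taken from the sample titles. The labels do not give the proportions that were mixed, so no proportion was assumed. Nothing in the labels says that the replicate pellets of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

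Per the labels, RNA was extracted from the pellets and sequenced as paired-end messenger RNA libraries on a NovaSeq instrument. RSEM 1.30 and Bowtie2 2.10 are named in the submitters' processing notes, which also name the builds GRCh38 and hg19 without saying what each was used for. The gene annotation and the strand setting are not given in the sources used here, and no coordinates are printed. The deposited table holds counts as whole numbers, 1 value per gene and library, with no normalization seen in its values. Since RSEM estimates counts, the deposited counts may be estimates that the authors rounded. Antisense and overlapping genes cannot be told apart without the strand setting, and reads of near-identical genes may have been divided between them.

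The table held 36552 genes by symbol, of which 8003 had no count in any library. XIST, TSIX and Y-linked genes, 105 in all, were left out before any test, which left 36447 genes. All columns matched 1 sample by name and no pair of columns was identical. Total counts per library ranged from 16590730 to 35080322. Where every library of a line had a count of 0, the line was set to 3 counts over its libraries and the fold is given as a lower bound. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

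Differential expression was tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was used with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjusted p under 0.05. One model with 6 group means was fitted to the 18 line libraries (17565 genes) and another to the 18 mixture libraries (16564 genes). Each line was compared with the mean log2 level of the other 5 lines, each breast cancer line with the mean of the other 2, and each mixture with the mean of the other 5 mixtures. A gene was counted above or below every other line when all 5 pairwise tests passed with a log2 fold change of at least 2 in size. A further model of all 36 libraries (18015 genes) compared the mean of the 6 mixtures with each line, and a gene was counted above or below all 6 lines when all 6 tests passed in that direction. The common biological coefficient of variation was 0.0909 in the lines, 0.128 in the mixtures and 0.112 in all libraries. Levels are CPM with TMM scaling within the 18 lines, within the 18 mixtures, or within all 36 libraries for the comparison of mixtures with all 6 lines, given as mean ± SD. Levels from different scalings are set side by side only as descriptions. The level of the other mixtures set against a mixture is their arithmetic mean, while the tests used mean log2 levels.

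RNA shares were estimated by non-negative least squares of each mixture library on the 6 mean line profiles. Linear CPM of the library total was used over 100 marker genes per line, each gene was divided by its highest line mean, and the 6 shares were rescaled to sum to 100%. These are shares of RNA, not of cells. Differences among mixtures were tested with a permutation test of the F statistic with 100000 resamples, and p was adjusted over the 6 lines. The linear prediction of a library is the sum of the line profiles weighted by its shares. It was compared with the measured library by Pearson correlation of log2(CPM + 1) across 17415 genes not used as markers, and genes are not independent replicates.

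A set of 27 gene lists was fixed before the data were examined. The lists cover luminal epithelial, basal epithelial, estrogen response, 17q12 HER2 amplicon, 17q23 amplicon, 20q13 amplicon, myeloid monocyte, T lymphocyte, B lymphocyte, pan-leukocyte, erythroid, mesenchymal stromal, endothelial, adipocyte and MHC class II genes. They also cover proliferation, immediate early, heat shock, unfolded protein and amino acid response, hypoxia and glycolysis, interferon response, NF-kB inflammatory, cholesterol synthesis, p53 target, cytosolic ribosomal protein, mitochondrially encoded and replication-dependent histone genes. Of the 27 lists 26 were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The remaining list, erythroid, had 1 measured member.

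The rule for named genes was also fixed before the data were examined. For each line it took the 4 genes above every other line with the highest mean CPM and the 1 gene below every other line with the highest mean CPM elsewhere. For each breast cancer line it took the 4 higher and 2 lower genes with the largest log2 fold change and at least 50 CPM on the higher side. For each mixture it took the 3 higher and 2 lower genes with the largest log2 fold change and at least 10 CPM over the mixtures. Outside the lines it took up to 10 genes on each side with at least 5 CPM. Mitochondrial genes, pseudogenes and genes with clone-based names were not named. List examples are the 3 measured members with the highest mean CPM in the group.

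Simulated counts with mean levels taken from these libraries, and the same spread for every gene, were used to test the methods. Library sizes were also taken from these libraries, except that the simulated mixtures for the shares all had the same depth. In the simulated comparisons of BT474 and Mix1, all groups shared the same mean profile except for the changed genes. Their false calls therefore do not cover groups that differ widely or libraries that stand apart. In the simulated comparison of BT474 with the other lines (16509 genes), 83.2% of genes changed by 0.5 on the log2 scale and 94.8% of those changed by 1 were recovered, and 5.5% of calls were false. In the simulated comparison of Mix1 with the other mixtures (16161 genes), 52.5% and 98% were recovered and 4.5% of calls were false. In the simulated comparison of mixtures with all 6 lines (17791 genes), 75% and 96% were recovered and no call was false. The changed genes there were drawn only from genes above a minimum mean level in the lines, so this recovery does not cover lower genes. Shares of simulated mixtures differed from the true ones by at most 1.17 percentage points. Those mixtures were sums of the same line profiles that were then fitted. The error therefore covers counting and spread only, not departures of real mixtures from a sum.

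Alternatives fixed before the data were examined were DESeq2 1.42.0, total-count scaling, no filter on low counts, all 36 samples in one model, the 9 breast cancer line samples alone, the replicate name as a block, leaving out each replicate in turn, 50 or 200 markers per line, all filtered genes in place of markers, no division of the genes, other pseudocounts and an estimated correlation for the lists. After the data were seen, alternatives were added without the 5 libraries that stood apart from both replicates of their group by a chi-square per gene above 15. The same alternatives were then also run for the counts of genes below every other line, the lists of Mix1, Mix5 and Mix6 were tested without the library of that mixture that stood apart, the fit of each pure library was repeated with markers chosen without it, and the departures from the linear prediction were computed with the shares from all filtered genes and from undivided genes. Share computations, tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.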

Results

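Gene expression was measured by messenger RNA sequencing in 36 frozen cell pellets, made to hold the cells of a solid tumour in varying proportions. The 6 pure groups were BT474, T47D and MCF7, which are luminal breast cancer lines, Thp1, a monocytic leukemia line, Jurkat, a T-cell leukemia line, and human mesenchymal stem cells (hMSC), cultured stromal cells. The other 6 groups, Mix1 to Mix6, were mixtures of these cells, and every group had 3 replicate pellets. Total counts ranged from 16590730 (Mix6 c) to 35080322 (Mix5 b) per library, and 16515 to 21852 genes were detected in a library. Thp1 replicate 2, Jurkat replicate 2, Mix1 a, Mix5 c and Mix6 c stood apart from both replicates of their group. Mitochondrial transcripts held 6.84% of the counts of Mix1 a against 3.86% and 4.25% in its replicates, 5.76% of Mix5 c against 3.78% and 4.25%, and 6.75% of Mix6 c against 4.56% and 4.47%.

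The pure cells were first compared with each other, since a mixture can be resolved only by genes that differ among its parts. Among the genes above every other line in BT474, ERBB2 of the amplicon on 17q12 had the highest level. This gene, the receptor tyrosine kinase HER2, reached 5790 ± 18.2 CPM (SD, n = 3), which was 20.9 times the level of T47D, the next line. LASP1, an actin-binding protein encoded nearby, was at 5500 ± 114 CPM or 4.89 times the next line, hMSC, and the proteasome subunit PSMD3 was at 2270 ± 73.3 CPM or 7.83 times Thp1. KRT7, a keratin of glandular epithelium, was at 1930 ± 11.9 CPM against 151 ± 13.2 in T47D. LGALS1, the lectin galectin-1, was lowest in BT474 at 0.698 ± 0.0331 CPM against 20.1 ± 2.96 in Jurkat.

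All 17 measured genes of the 17q12 list were higher in BT474 than the mean of the other 5 lines (camera adjusted p = 1.38e-11), among them MED1, a Mediator subunit, with a log2 fold change of 3.78 ± 0.08 (SE). Of the 30 luminal epithelial genes 29 were higher and 1 lower (camera adjusted p = 1.02e-15), with the keratins KRT8 at 2390 ± 13.8 CPM and KRT19 at 1590 ± 52.3 CPM. The 17q23 and 20q13 lists were higher as well, 16 of 18 and 15 of 18 genes (camera adjusted p = 1.3e-05 for each). Interferon response genes went the other way, with 17 of 23 lower and 1 higher (camera adjusted p = 6.92e-06). STAT1, which carries the interferon signal to the nucleus, differed by −0.95 ± 0.05, at 102 CPM against means from 49.4 to 1780 CPM in the other lines. MX2, an antiviral GTPase, was the member that was higher, by 3.08 ± 0.13. Of 39 cytosolic ribosomal protein genes 37 were lower (camera adjusted p = 2.33e-10), and all 13 mitochondrially encoded genes were higher (camera adjusted p = 0.000115). These 2 calls were lost with an estimated correlation (adjusted p = 0.317 and adjusted p = 0.283 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. In the edgeR test 12334 of 17565 genes passed, 7214 higher and 5120 lower, and 310 genes were above every other line and 232 below.

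Among the genes above every other line in T47D were the receptors of prolactin and progesterone, though the estrogen response list was not called against the mean of BT474 and MCF7 (camera adjusted p = 0.445, 12 of 21 higher and 8 lower). PRLR, the prolactin receptor, was at 2240 ± 351 CPM (n = 3), 7.78 times the level of BT474. PGR, the progesterone receptor and a target of the estrogen receptor, was at 697 ± 99.2 CPM, 27.9 times BT474, and TRPS1, a GATA-type repressor, was at 806 ± 107 CPM, 5.33 times MCF7. MGP, a matrix protein that inhibits calcification, was at 1240 ± 127 CPM against 18.5 ± 1.38 in BT474. SPARC, a collagen-binding matrix protein, had no count in T47D, so its level was at least 3.7-fold lower than in BT474 (0.146 ± 0.0201 CPM), the next lowest line.

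Of the 21 estrogen response genes 18 were higher in T47D and 3 lower (camera adjusted p = 6.17e-06), with STC2, a secreted glycoprotein, at 1500 ± 42.8 CPM and FKBP4, a co-chaperone of steroid receptors, at 803 ± 23.5 CPM. Of the 30 luminal genes 28 were higher and 1 lower (camera adjusted p = 2.79e-15), with KRT8 at 5610 ± 296 CPM. Proliferation genes were higher in 24 of 28 cases (camera adjusted p = 0.00444), and 17 of 23 hypoxia and glycolysis genes were lower (camera adjusted p = 0.000812). MHC class II genes, which present peptides to helper T cells, were higher in 7 of 10 cases (camera adjusted p = 0.0493, and adjusted p = 0.181 with an estimated correlation). Their levels were low, with the chaperone HLA-DMA at 19.7 ± 2.05 CPM and the invariant chain CD74 at 14.7 ± 1.25 CPM. Immediate early genes were lower in 19 of 26 cases (camera adjusted p = 0.00509, and adjusted p = 0.236 with an estimated correlation). The counts adjusted over the list alone were the same. By edgeR, 12471 genes passed, 7386 higher and 5085 lower, and 323 genes were above every other line and 152 below.

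MCF7 carried high levels of genes on 17q23 and 20q13. SULF2, an extracellular sulfatase encoded on 20q13, was at 1160 ± 13.5 CPM (n = 3), 11.4 times hMSC. PSMD6, a proteasome subunit, was at 1300 ± 15.4 CPM, 10.4 times Thp1. The keratin KRT80 was at 1160 ± 23.4 CPM, 6.8 times T47D, and SPTSSB, a subunit of serine palmitoyltransferase, at 1100 ± 5.42 CPM, 15.5 times T47D. ANXA6, a membrane-binding annexin, was lowest in MCF7 at 19 ± 1.22 CPM against 90.1 ± 3.66 in BT474.

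All 18 genes of the 17q23 list were higher in MCF7 than the mean of the other 5 lines (camera adjusted p = 8.5e-12), as were 16 of 18 on the 20q13 list (camera adjusted p = 1.93e-07). TRIM37, a ubiquitin ligase of 17q23, differed by 3.91 ± 0.04 on the log2 scale, and NCOA3, a coactivator of the estrogen receptor on 20q13, by 4.16 ± 0.06. Interferon response genes were higher in 22 of 23 cases (camera adjusted p = 2.55e-07), with the ubiquitin-like protein ISG15 at 339 ± 19.3 CPM. Targets of p53 were higher in 19 of 20 cases (camera adjusted p = 2.55e-07), among them the cell cycle inhibitor CDKN1A at 408 ± 16.6 CPM and the p53 ubiquitin ligase MDM2 at 185 ± 5.09 CPM. All 20 replication-dependent histone genes were higher (camera adjusted p = 4.04e-07), with H2BC21 at 165 ± 6.33 CPM, though reads of these near-identical genes may be divided between copies. Estrogen response genes were higher in 19 of 21 cases and basal epithelial genes in 9 of 11 (camera adjusted p = 4.04e-07 and camera adjusted p = 0.00015). Immediate early genes were higher in 21 of 26 cases (camera adjusted p = 0.000253, and adjusted p = 0.0983 with an estimated correlation). The counts adjusted over the list alone were the same. A total of 12210 genes passed the edgeR test, 7414 higher and 4796 lower, and 313 genes were above every other line and 96 below.

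Granule proteins of myeloid cells were among the genes above every other line in Thp1. MPO, the myeloperoxidase of primary granules, was at 12100 ± 185 CPM (n = 3) against 0.32 ± 0.0399 in BT474, the next line. PRG2, the major basic protein of eosinophil granules, was at 1930 ± 52.6 CPM against 0.15 ± 0.146 in Jurkat. SRGN, the proteoglycan that packs granules, was at 2910 ± 107 CPM, 7.66 times hMSC, and the ribosomal protein gene RPL18 was at 3510 ± 125 CPM, 5.03 times MCF7. The keratin KRT18 was lowest in Thp1 at 0.344 ± 0.222 CPM against 2.59 ± 0.722 in Jurkat.

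Of the 30 measured myeloid genes 28 were higher in Thp1 and none passed as lower (camera adjusted p = 3.85e-13), including the granule protease PRTN3 at 1390 ± 82.3 CPM and the transcription factor CEBPA at 233 ± 5.53 CPM. The 20 pan-leukocyte genes were higher in 19 cases (camera adjusted p = 1.19e-11), with the actin bundler LCP1 at 1610 ± 31.2 CPM. All 39 ribosomal protein genes were higher (camera adjusted p = 4.46e-09), with a median log2 fold change of 1.02 and RPS6 at 4110 ± 280 CPM. With an estimated correlation these 3 calls were lost (adjusted p = 0.0562, adjusted p = 0.0562 and adjusted p = 0.376 with an estimated correlation). Proliferation genes were higher in 26 of 28 cases (camera adjusted p = 4.46e-09) and p53 targets were lower in 15 of 20 (camera adjusted p = 0.00085), both called with an estimated correlation too. Lists of cells that were not mixed in were not called: B lymphocyte genes passed as higher in 5 of 9 cases and lower in 1 (camera adjusted p = 0.182), endothelial genes in 1 and 3 of 10 (camera adjusted p = 0.765) and adipocyte genes in 2 and 3 of 8 (camera adjusted p = 0.916). Neither were cholesterol synthesis, with 10 of 24 genes higher and 10 lower (camera adjusted p = 0.765), nor heat shock, with 10 of 17 higher and 5 lower (camera adjusted p = 0.263). Adjusted over the list alone, 11 cholesterol genes were lower and the other counts were the same. Thp1 replicate 2 also held transcripts of skeletal muscle, at a median of 39.3 CPM over a list of 35 genes chosen after the data were seen, against 0.147 and 0 CPM in its replicates. The edgeR test called 12686 genes, 6492 higher and 6194 lower, and 397 genes were above every other line and 923 below.

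In Jurkat the genes above every other line included some of T-cell signalling. LCK, the kinase of the T-cell receptor, was at 675 ± 32 CPM (n = 3) against 0.135 ± 0.0902 in T47D. ADA, the adenosine deaminase of lymphocytes, was at 964 ± 21.4 CPM, 68.6 times hMSC, and the cell cycle kinase CDK6 at 807 ± 114 CPM, 8.07 times hMSC. PTPRC, the leukocyte phosphatase CD45, was at 659 ± 22.8 CPM, 14.5 times Thp1. COL1A1, a chain of type I collagen, was at 3.68 ± 0.259 CPM against 21.5 ± 1.12 in MCF7, below every other line by edgeR (highest adjusted p = 0.0455). That call was lost with total-count scaling (edgeR adjusted p = 0.0589) and without any 1 library of the lines other than Thp1 (edgeR adjusted p = 0.0525 to 0.103). It rested on Thp1 replicate 2, because Thp1 was at 50 ± 86.4 CPM, and without that library Jurkat lay above Thp1 by 5.13 on the log2 scale (edgeR adjusted p = 2.28e-13).

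All 31 measured T lymphocyte genes were higher in Jurkat (camera adjusted p = 1.36e-17), among them CD3E, a chain of the T-cell receptor complex, at 448 ± 27.1 CPM and the transcription factor LEF1 at 475 ± 54.2 CPM. Proliferation genes were higher in 26 of 28 cases (camera adjusted p = 5.23e-09), with the topoisomerase TOP2A at 618 ± 41.7 CPM and the ribonucleotide reductase subunit RRM2 at 429 ± 14.8 CPM. Pan-leukocyte genes were higher in 19 of 20 cases (camera adjusted p = 2.86e-11, and adjusted p = 0.0564 with an estimated correlation), with ARHGDIB, an inhibitor of Rho GTPases, at 1240 ± 57.6 CPM. The counts adjusted over the list alone were the same. In the edgeR test 12490 genes passed, 7263 higher and 5227 lower, and 445 genes were above every other line and 446 below. Of the genes that passed 58.2% were higher with TMM scaling and 68.9% with total-count scaling.

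The 4 genes of highest level among those above every other line in hMSC encode matrix proteins. FN1, the matrix glycoprotein fibronectin, was at 96100 ± 1500 CPM (n = 3), 1260 times MCF7, and COL1A1 at 50100 ± 1250 CPM, 795 times BT474. COL1A2, the other chain of type I collagen, was at 30000 ± 324 CPM against 4.28 ± 7.41 in Thp1, where it came from replicate 2. THBS1, the matrix protein thrombospondin-1, was at 10500 ± 80.5 CPM, 16.7 times MCF7. LCP1 was lowest in hMSC, with 3 counts over 3 libraries (0.0846 ± 0.147 CPM) against 5.14 ± 1.09 CPM in BT474.

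All 40 mesenchymal stromal genes were higher in hMSC (camera adjusted p = 7.53e-20, and adjusted p = 0.0996 with an estimated correlation). All 28 proliferation genes were lower (camera adjusted p = 4.65e-18, and adjusted p = 0.000203 with an estimated correlation), with TOP2A at 62.8 ± 4 CPM against 226 CPM or more in each other line and MCM6, a subunit of the replicative helicase, lower by −2.04 ± 0.05 on the log2 scale. Genes of the unfolded protein and amino acid response were higher in 17 of 19 cases, those of NF-kB inflammation in 15 of 19 and p53 targets in 17 of 20 (camera adjusted p = 0.000116, camera adjusted p = 0.00769 and camera adjusted p = 0.0012). These 3 calls were lost with an estimated correlation (adjusted p = 0.122, adjusted p = 0.14 and adjusted p = 0.0788 with an estimated correlation). The counts adjusted over the list alone were the same. ICAM1, an adhesion molecule induced by NF-kB, differed by 3.85 ± 0.08 and the mitochondrial superoxide dismutase SOD2 by 2.3 ± 0.04. Smaller differences depended on the scaling: the chaperone HSPA5 was higher by 0.48 ± 0.04, the transcription factor ATF4 by 0.64 ± 0.05 and NFKB1 by 0.24 ± 0.07 with TMM, and with total-count scaling they were at −0.18, −0.03 and −0.43. Under total counts 14 unfolded protein response genes were higher and 4 lower, 11 NF-kB genes were higher and 4 lower, and 12 p53 targets were higher and 6 lower. NFKB1 was not called without hMSC replicate 1 (log2 fold change 0.20, edgeR adjusted p = 0.0528). By edgeR, 13074 genes passed, 7360 higher and 5714 lower, and 1187 genes were above every other line and 465 below, with 764 below under total-count scaling. The share of higher genes was 56.3% with TMM and 38% with total counts. This is because TMM moved the difference between hMSC and the mean of the other lines by 0.66 on the log2 scale. The same difference moved by −0.21 for T47D, −0.12 for MCF7 and −0.31 for Jurkat.

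The 3 breast cancer lines were then compared with each other, as the parts of a mixture most alike. BT474 was set apart from T47D and MCF7 by the 17q12 genes, of which all 17 were higher (camera adjusted p = 3.04e-13), ERBB2 by 5.11 ± 0.06 and PSMD3 by 3.7 ± 0.04 on the log2 scale. MXRA5, a matrix-remodelling protein, was at 166 ± 5.94 CPM (n = 3) with no count in the other lines, at least 3430-fold higher, and STAC2, an adaptor of muscle and nerve calcium channels, was at 97.3 ± 5.18 CPM, at least 2010-fold higher. ALOX15B, a lipoxygenase, was at 130 ± 3.12 CPM against 2 counts in T47D and none in MCF7, and the chemokine CX3CL1 at 78 ± 1.9 CPM against 1 count in MCF7 and none in T47D. The potassium channel KCNK2 and the peroxisomal membrane protein PXMP4 had no count in BT474 and were at 175 ± 6.58 and 182 ± 4.41 CPM in T47D and at 39.2 ± 0.354 and 16.6 ± 1.17 CPM in MCF7, so they were at least 896-fold and 378-fold lower in BT474 than in MCF7. Interferon response genes were lower in 18 of 23 cases and higher in 3 (camera adjusted p = 2.63e-05), STAT1 by −0.99 ± 0.05, with MX2 higher by 4.82 ± 0.18. Here the mean of the other lines holds the high level of MCF7. STAT1 was at 102 CPM in BT474 against 104 in T47D and 392 in MCF7. Adjusted over the list alone the counts were the same. A total of 12167 genes passed the edgeR test, 6284 higher and 5883 lower.

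T47D was lower in genes of 17q23 and 20q13 than the mean of the other breast cancer lines. All 18 genes of the 17q23 list were lower (camera adjusted p = 3.52e-10), as were 15 of 18 on the 20q13 list (camera adjusted p = 5.18e-07) and 12 of 17 on the 17q12 list (camera adjusted p = 0.000332). On 17q12 the mean holds the high level of BT474, and ERBB2 was at 277 ± 2.48 CPM in T47D against 102 ± 4.35 in MCF7. ZNF217, a zinc finger protein of 20q13, differed by −1.86 ± 0.09, and the kinase AURKA by −0.29 ± 0.06, at 160 CPM between MCF7 (129) and BT474 (296). SERPINA6, the carrier of corticosteroids, was at 241 ± 5.5 CPM (n = 3) in T47D with no count in the others, at least 5000-fold higher. The G protein subunit GNG11 at 137 ± 14.5 CPM and the myosin light chain MYL9 at 113 ± 9.17 CPM also had no count in the others, at least 2830-fold and 2350-fold higher. PIP, the prolactin-induced protein, was at 341 ± 26.4 CPM against 0.2 ± 0.108 in BT474. The kinesin KIF1A and the imprinted gene MEST had no count in T47D, at least 935-fold and 1620-fold lower than in MCF7 (37 ± 2.53 and 64.3 ± 4.67 CPM). MHC class II genes were higher in 8 of 10 cases (camera adjusted p = 0.0197, and adjusted p = 0.1 with an estimated correlation), CD74 by 8.87 ± 0.33. Adjusted over the list alone the counts were the same. The edgeR test called 12120 genes, 6303 higher and 5817 lower.

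MCF7 differed from BT474 and T47D by interferon response genes, of which 22 of 23 were higher (camera adjusted p = 1.26e-09), ISG15 by 8.9 ± 0.14 and the mitochondrial protein IFI6 by 7.1 ± 0.08 on the log2 scale. Targets of p53 were higher in 19 of 20 cases (camera adjusted p = 8.2e-08), CDKN1A by 4.34 ± 0.05, while proliferation genes were lower in 23 of 28 (camera adjusted p = 2.36e-06). The 2 proliferation genes that were higher were MKI67, the Ki-67 antigen, by 0.38 ± 0.11, and MCM7, a helicase subunit, by 0.13 ± 0.05, which was not called without MCF7 replicate 2 (0.10, edgeR adjusted p = 0.122) or without the filter on low counts (0.12, edgeR adjusted p = 0.0741). Genes on 17q23 were higher in 17 of 18 cases (camera adjusted p = 1.81e-09), those on 17q12 lower in 16 of 17 (camera adjusted p = 1.81e-09), and histone genes higher in 19 of 20 (camera adjusted p = 2.26e-05). The long noncoding RNA LINC00052 was at 85.2 ± 3.26 CPM (n = 3) against 3 counts in T47D and none in BT474, and TSPYL5, a nucleosome assembly protein, at 90.8 ± 2.85 CPM against 0.0816 ± 0.108 in BT474. The matrix protein HMCN1 was at 179 ± 7.96 CPM against 0.744 ± 0.192 in T47D, and the protocadherin PCDH10 at 128 ± 6.16 CPM against 0.422 ± 0.347 in BT474. The calponin CNN3 and the iron exporter SLC40A1 had no count in MCF7, at least 2280-fold and 814-fold lower than in BT474 (110 ± 2.4 and 39.3 ± 3.9 CPM). Adjusted over the list alone the counts were the same. In the edgeR test 12104 genes passed, 6460 higher and 5644 lower.

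The mixtures were then resolved into RNA shares of the 6 cell types, the quantity that a deconvolution method estimates. T47D held 70.6 ± 1.28% (SD, n = 3) of the RNA of Mix1 and 9.2 ± 0.33% of Mix2, and BT474 held 68.9 ± 1.28% of Mix2 and 18.5 ± 1.86% of Mix5. MCF7 ranged most in ratio, from 1.67 ± 0.05% in Mix1 to 40.5 ± 0.93% in Mix5. The 3 breast cancer lines together held between 85.9 ± 1.11% (Mix6) and 90.7 ± 1.12% (Mix1). The balance of Thp1 and Jurkat differed between 2 sets of mixtures. The ratio of Thp1 to Jurkat RNA was near or below 1 in Mix1, Mix3 and Mix5 (0.78 ± 0.07, 0.87 ± 0.08 and 1 ± 0.02). It was 3.94 ± 0.26, 3.68 ± 0.37 and 4.36 ± 0.52 in Mix2, Mix4 and Mix6. Shares of Thp1 lay between 3.81 ± 0.68% (Mix1) and 9.36 ± 0.96% (Mix6), of Jurkat between 2.15 ± 0.04% (Mix6) and 5.66 ± 0.2% (Mix5), and of hMSC between 0.56 ± 0.07% (Mix4) and 2.55 ± 0.2% (Mix6). The remaining shares of the breast cancer lines were 18.5 ± 0.72% BT474 in Mix1, 9.74 ± 1.39% MCF7 in Mix2 and 28.6 ± 0.84% T47D in Mix5. In Mix3 they were 27.5 ± 1.44% BT474, 40.4 ± 1.79% T47D and 19 ± 1.17% MCF7. The same lines held 35.9 ± 0.54%, 30.7 ± 0.36% and 21.4 ± 0.73% in Mix4, and 25.6 ± 0.91%, 51.6 ± 0.73% and 8.76 ± 1% in Mix6.

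Each line's share differed among the 6 mixtures by more than the spread between replicates. The permutation test of the F statistic, one-sided for large F and with 100000 resamples, gave p = 1e-05 for BT474, T47D, MCF7 and hMSC, the smallest that these resamples can give, p = 2e-05 for Jurkat and p = 5e-05 for Thp1, all at most 5e-05 after adjustment over the 6 lines. The hMSC share depended on the genes used: its range among mixtures was 1.99 percentage points with the markers, 0.74 without dividing each gene by its highest line mean and 3.63 with all filtered genes. Each pure library was also fitted in the same way on profiles that left it out. The share of its own line was then 99.5% or more, except for Thp1 replicate 2, where the fit failed, with 68.3% and coefficients that summed to 39.7. Of the 100 Thp1 markers 6 were muscle genes, chosen with that library included. With markers chosen without the fitted library its own share was 99.1%, with a sum of 1.05, and that of the other libraries 99.2% or more. Without Thp1 replicate 2 the Thp1 shares were between 4.02% (Mix1) and 9.85% (Mix6).

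**Figure D1:**
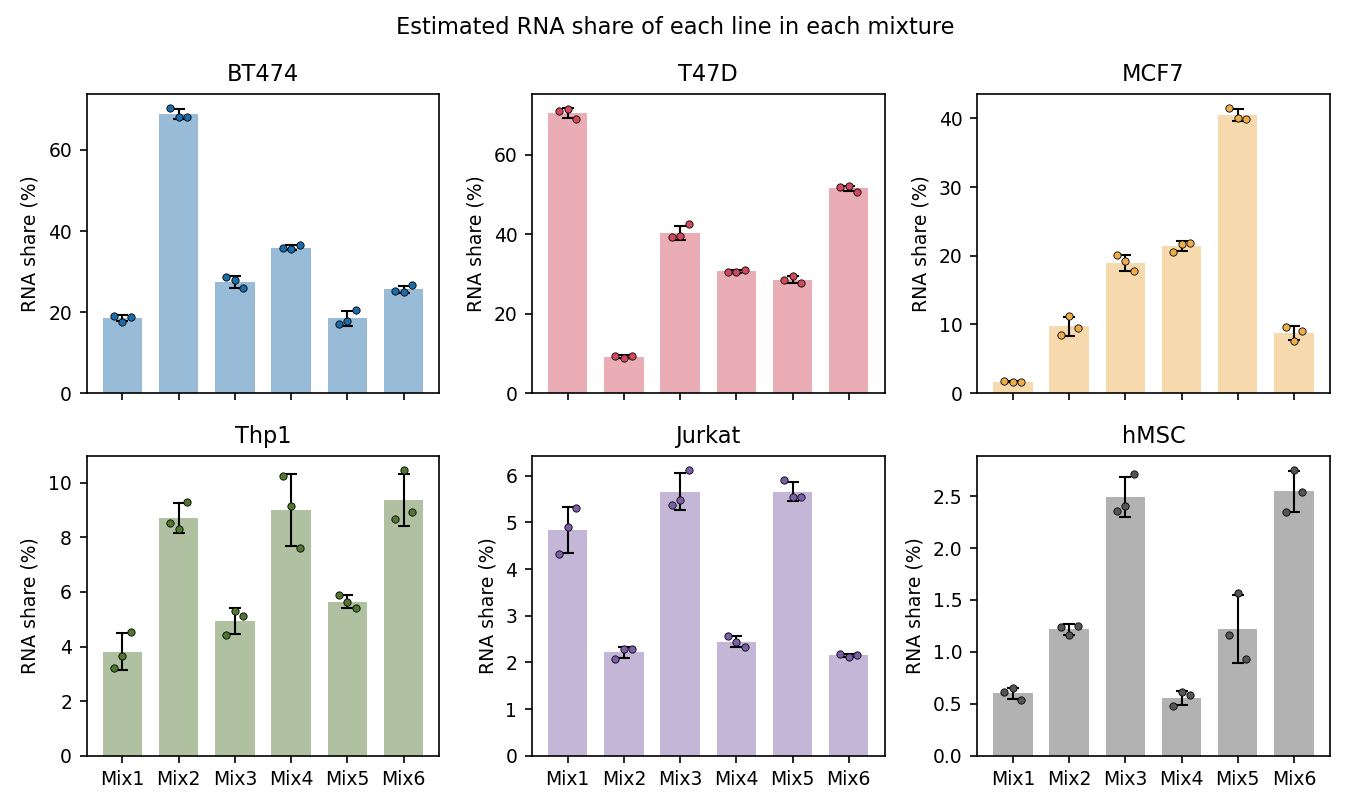
Estimated RNA share in percent (vertical axis, a separate scale for each of the 6 panels) of each pure cell type in Mix1 to Mix6 (horizontal axis); bars are means, error bars are SD and points are the 3 replicate libraries. T47D stands at 70.6% in Mix1 and 9.2% in Mix2, and Jurkat lies between 2.15% and 5.66%.

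Among the mixtures 9566 of 16564 genes differed by the edgeR F test, and Mix1 was compared first with the mean of the other 5. Mix1 differed most in the following genes by the rule for names. KCNH1, a potassium channel, was at 37.4 ± 8.67 CPM (n = 3) against 13.3 in the others and 30.7 CPM in pure T47D (41.7 in hMSC), and GRPR, the receptor of gastrin-releasing peptide, at 29.3 ± 6.49 against 10.7 CPM. The MCF7 transcript LINC00052 was at 2.83 ± 0.567 against 42 CPM, a log2 fold change of −3.7 ± 0.15, and SHH, a morphogen, at 1.33 ± 0.732 against 18.1 CPM. EIF3CL, a near-identical copy of EIF3C, was at 324 ± 548 CPM, a value from Mix1 a that is uncertain, since without Mix1 a the log2 fold change was 0.35 (edgeR adjusted p = 0.719).

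Of the 18 genes of the 17q23 list 16 were lower in Mix1 (camera adjusted p = 2.55e-21), such as VMP1, an autophagy protein, by −0.83 ± 0.07. T lymphocyte genes were higher in 23 of 28 cases, 25 adjusted over the list alone (camera adjusted p = 3.92e-06), LCK by 0.74 ± 0.08. Mesenchymal genes were lower in 30 of 40 cases and higher in 5 (8 without Mix1 a), 6 adjusted over the list alone (camera adjusted p = 7.49e-09, and adjusted p = 0.202 with an estimated correlation), FN1 by −0.85 ± 0.16. THBS1 was higher by 0.48 ± 0.12, and without Mix1 a, the library with 6.84% mitochondrial counts, by 0.19 (edgeR adjusted p = 0.114). By edgeR, 7725 genes passed, 3876 higher and 3849 lower.

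In Mix2 genes of 17q12 were high. All 16 measured genes of the 17q12 list were higher, also adjusted over the list alone (camera adjusted p = 5.17e-35), with ERBB2 at 4730 ± 324 CPM (n = 3), a log2 fold change of 1.46 ± 0.05, and PSMD3 by 1.29 ± 0.06. TPPP3, a tubulin-binding protein, was at 29.8 ± 3.78 against 9.21 CPM in the other mixtures, and the homeobox gene HOXB13 at 28.5 ± 2.54 against 8.88 CPM. The T47D genes PCDHB5, a protocadherin, and SYT8, a synaptotagmin, were lower, at 2.76 ± 0.754 against 15.1 CPM and 2.53 ± 0.581 against 12.6 CPM. MATR3, a nuclear matrix protein with overlapping gene models and hence uncertain counts, was at 40.2 ± 8.89 against 12.8 CPM.

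Estrogen response genes were lower in 13 of 21 cases in Mix2 and higher in 2, 3 adjusted over the list alone (camera adjusted p = 2.22e-08), FKBP4 by −0.38 ± 0.05. T lymphocyte genes were lower in 18 of 28 cases, 21 adjusted over the list alone (camera adjusted p = 1.17e-05), and their largest member by level was GATA3, also on the luminal list, by −1.35 ± 0.06. A total of 7931 genes passed the edgeR test, 4384 higher and 3547 lower. The share of higher genes was 55.3% with TMM and 42.6% with total-count scaling.

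Mix3 was high in stromal and T-cell genes. Mesenchymal genes were higher in 29 of 40 cases, 34 adjusted over the list alone (camera adjusted p = 3.02e-111), with FN1 at 669 ± 170 CPM (n = 3), a log2 fold change of 1.08 ± 0.14, and COL1A1 at 313 ± 49.3 CPM, 0.93 ± 0.1, which was not called in the fit of all 36 samples (0.931, edgeR adjusted p = 0.444). POSTN, the matrix protein periostin, was at 27.1 ± 3.89 against 12.1 CPM, and SERPINE1, the inhibitor of plasminogen activators, at 101 ± 10.5 against 48.1 CPM. IGFBP7, a secreted binding protein, was at 39.3 ± 2.44 against 17.7 CPM. T lymphocyte genes were higher in 19 of 28 cases, 22 adjusted over the list alone (camera adjusted p = 3.22e-37), LCK by 0.66 ± 0.08. Of 26 lists 13 were called in Mix3 by camera and 4 with an estimated correlation, among them estrogen response genes, higher in 2 of 21 cases and 7 adjusted over the list alone (camera adjusted p = 9.56e-05). The Thp1 genes PLTP, a phospholipid transfer protein, and LAT2, an adaptor of immune receptors, were lower, at 11.8 ± 0.133 against 20.8 CPM and 10.8 ± 0.302 against 18.8 CPM. The IGFBP7 call did not hold without any 1 of the Mix3 replicates (edgeR adjusted p = 0.0684, 0.0653 and 0.109 without a, b and c). The edgeR test called 423 genes, 374 higher and 49 lower. The number was 682 with DESeq2, 225, 248 and 202 without Mix3 a, b and c, and 733 without Mix1 a.

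Mix4 was low in stromal and T-cell genes. Mesenchymal genes were lower in 27 of 40 cases, 28 adjusted over the list alone (camera adjusted p = 1.01e-68), with FN1 at 174 ± 17.7 CPM (n = 3), a log2 fold change of −1.26 ± 0.17. RGS4, a regulator of G protein signalling, was at 3.6 ± 0.152 against 11.4 CPM, and FBN1, the microfibril protein fibrillin-1, at 8.35 ± 1.34 against 25 CPM. T lymphocyte genes were lower in 14 of 28 cases, 19 adjusted over the list alone (camera adjusted p = 7.21e-23), LCK by −0.72 ± 0.09. LEF1 was lower by −0.48 ± 0.11, a call that did not hold without Mix4 b or c (edgeR adjusted p = 0.197 and 0.243). The MCF7 genes ADAMTS19, a metalloprotease, SHH and LINC00052 were higher by 1.1 ± 0.09, 1.09 ± 0.15 and 1.08 ± 0.1 on the log2 scale. Their levels were 29.6 ± 1.13 against 21.5, 19.4 ± 0.33 against 14.5 and 44.6 ± 2.8 against 33.7 CPM. The mean log2 level of the other mixtures holds the low level of Mix1 (SHH at 1.33 and LINC00052 at 2.83 CPM). SHH was higher still in Mix5, at 37.5 CPM. Genes on 17q23 were higher in 9 of 18 cases, 12 adjusted over the list alone (camera adjusted p = 2.7e-21). In the edgeR test 530 genes passed, 323 higher and 207 lower. The number was 262, 253 and 263 without Mix4 a, b and c, and 983 without Mix1 a.

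Mix5 was high in genes of 17q23 and low in genes of 17q12. SHH was at 37.5 ± 3.38 CPM (n = 3) against 10.9 in the other mixtures and 18.4 in pure MCF7. NECAB1, a calcium-binding neuronal protein, was at 30.4 ± 1.4 against 8.97 CPM, and GFRA1, a coreceptor for GDNF, at 423 ± 29.2 against 127 CPM, a log2 fold change of 2.14 ± 0.07. SLC6A11, a GABA transporter, was lower at 4.77 ± 0.412 against 11.2 CPM. MATR3 was at 7.24 ± 5.39 against 19.4 CPM (edgeR adjusted p = 0.0487), a call lost in most alternatives, among them DESeq2 (adjusted p = 0.0579), where its counts are uncertain in any case.

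All 16 genes of the 17q12 list were lower in Mix5 (camera adjusted p = 1.77e-19), ERBB2 by −0.85 ± 0.06, while 14 of 18 on 17q23 were higher (camera adjusted p = 1.94e-28), TRIM37 by 1.09 ± 0.06 and the deubiquitinase USP32 by 1.05 ± 0.09. These counts were the same adjusted over the list alone. Histone genes were higher in 15 of 20 cases, 16 adjusted over the list alone (camera adjusted p = 5.89e-08), H2BC21 by 1.01 ± 0.06 and H2BC5 by 0.31 ± 0.11 (edgeR adjusted p = 0.0494). H2BC5 was not called with total-count scaling (edgeR adjusted p = 0.0847). Its call was also lost without most single libraries of Mix2 to Mix6, such as Mix4 c or Mix5 a (edgeR adjusted p = 0.0569 and 0.293). T lymphocyte genes were higher in 22 of 28 cases, 23 adjusted over the list alone (camera adjusted p = 1.36e-11). By edgeR, 4717 genes passed, 2376 higher and 2341 lower. Mix5 c held 5.76% mitochondrial counts.

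Mix6 was high in stromal and myeloid genes and low in T-cell genes. Mesenchymal genes were higher in 31 of 40 cases, 34 adjusted over the list alone (camera adjusted p = 6.43e-69), with FN1 at 687 ± 19.6 CPM (n = 3) and COL1A1 at 314 ± 3.95 CPM, which was not called in the fit of all 36 samples (edgeR adjusted p = 0.267). RGS4 was at 18.9 ± 1.42 against 8.35 CPM, SERPINE1 at 101 ± 6.55 against 48.2 CPM and SERPINB2, another inhibitor of plasminogen activation, at 26.6 ± 1.07 against 12 CPM. Myeloid genes were higher in 9 of 27 cases, 18 adjusted over the list alone (camera adjusted p = 1.41e-12), with MPO at 1270 ± 137 CPM, a log2 fold change of 0.62 ± 0.07. T lymphocyte genes were lower in 19 of 28 cases and higher in 1, with 22 and 1 adjusted over the list alone (camera adjusted p = 1.95e-19). BCL11B, a transcription factor of T-cell commitment, was at 5.48 ± 0.395 against 12.3 CPM and the kinase ZAP70 at 6.09 ± 1.17 against 11.6 CPM. A total of 1884 genes passed the edgeR test, 1085 higher and 799 lower. The number was 1031, 770 and 1067 without Mix6 a, b and c and 3332 without Mix1 a, and the share of higher genes was 57.6%, with 70.7% under total-count scaling, 69.8% without Mix5 b and 73% without Mix6 b.

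**Figure D2:**
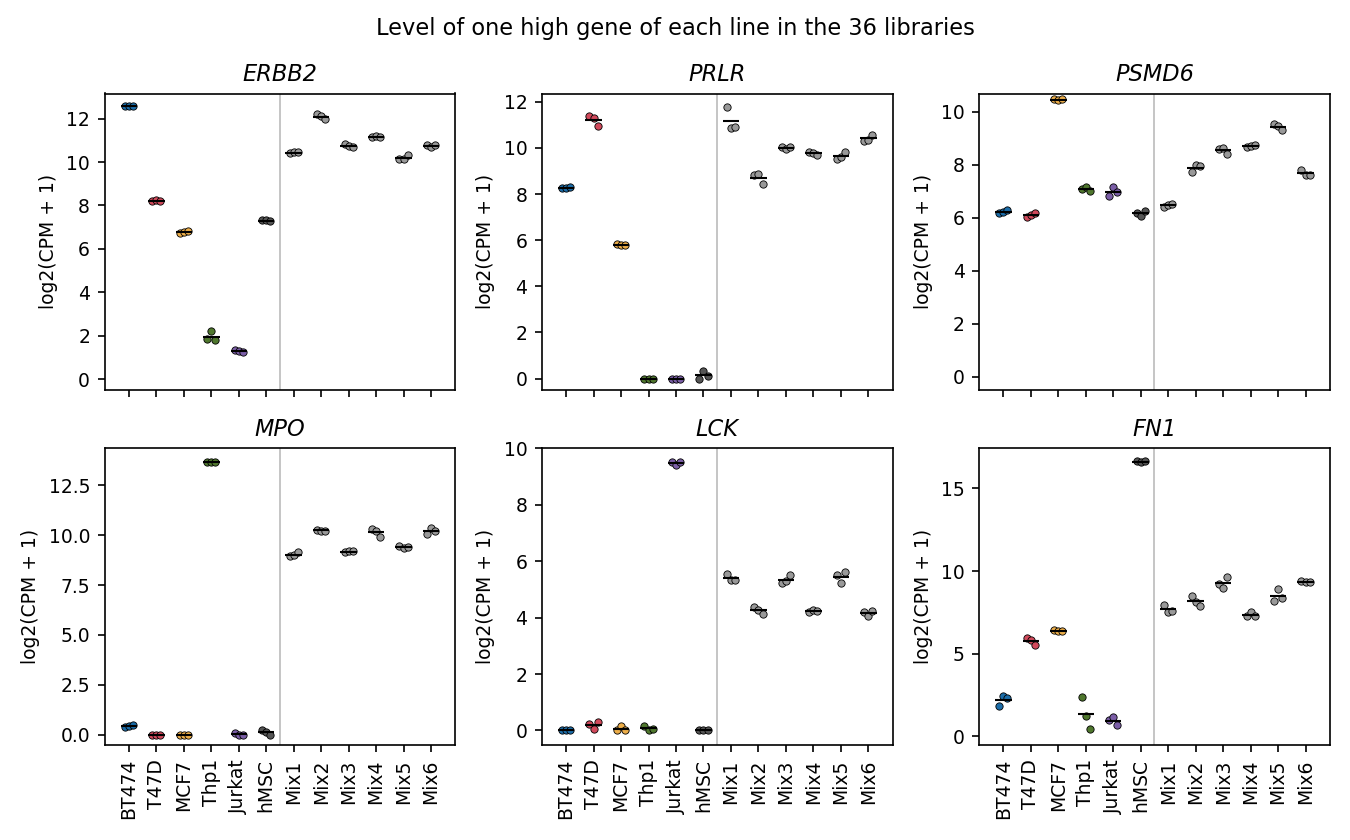
Level of ERBB2, PRLR, PSMD6, MPO, LCK and FN1 as log2(CPM + 1) with TMM scaling over all 36 libraries (vertical axis, a separate scale for each panel) in the 6 pure groups and 6 mixtures (horizontal axis); points are libraries and horizontal lines are means of 3. LCK and MPO are near 0 in the other pure cells and at intermediate levels in each mixture.

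Whether a mixture holds more than the sum of its parts was examined last. A sum of the line profiles weighted by the estimated shares correlated with the measured mixtures at r = 0.994 ± 0.004 (SD over 18 libraries) across 17415 genes. The correlation of a mixture library with its closest single line was 0.961 ± 0.009 and with its own replicates 0.993 ± 0.004. In the mean of the 6 mixtures 5 of 18015 genes lay above all 6 lines. Genes above the lines only in some mixtures were not counted. SHH, for example, was at 37.5 CPM in Mix5 and at 18.4 CPM in pure MCF7, its highest line, in separate scalings. HES1, a transcriptional repressor of the Notch pathway, was at 152 ± 28.9 CPM (SD, n = 18) against 71.6 ± 2.03 in BT474, the nearest line, a log2 fold change of 1.08 (edgeR adjusted p = 4.59e-08). The immediate early gene EGR3 was at 11 ± 7.53 CPM against 5.08 ± 0.371 in MCF7, and it ranged from 1.23 to 26.8 CPM among mixture libraries. ACACB, an acetyl-CoA carboxylase, was at 20.8 ± 12 CPM against 12.7 ± 1.54 in Jurkat (7.68 to 50.3 among libraries), and GDAP1, a protein of the outer mitochondrial membrane, at 45.6 ± 14.8 against 34.7 ± 2.58 in T47D (26.9 to 75.1). GLIPR1L2, which was outside the rule for named genes and is named after its values were seen, was at 2.48 CPM.

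PHF23, a PHD finger protein, was the 1 gene below all 6 lines, at 36.8 ± 2.68 CPM against 41.4 ± 5.23 in T47D (log2 fold change −0.17, edgeR adjusted p = 0.0242). It was not called with total-count scaling (edgeR adjusted p = 0.555) or without T47D replicate 3 (edgeR adjusted p = 0.507). EGR3 was the only list member among these genes, 1 of 26 immediate early genes (one-sided Fisher's exact test, adjusted p = 0.194 over 27 lists), and the 1 measured erythroid gene was not among them. TMM moved the difference between the mixtures and a line by −0.70 on the log2 scale for hMSC, −0.22 for Thp1 and −0.12 for BT474 relative to total counts.

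**Figure D3:**
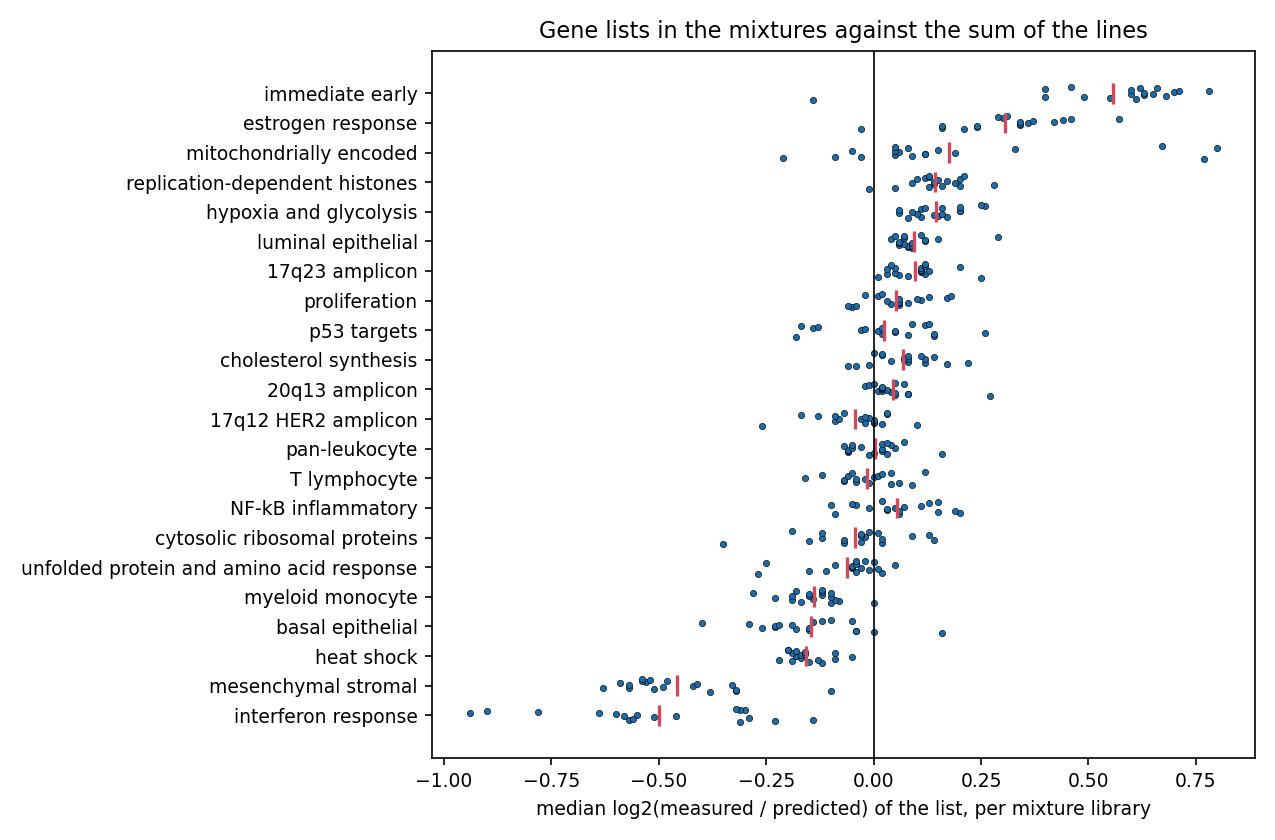
Median log2 ratio of measured to predicted level of 22 gene lists (vertical axis) in each mixture library (horizontal axis); points are the 18 libraries and red lines are means over them. The interferon response list lies below 0 in all 18 libraries and the immediate early list above 0 in 17.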

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

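The lists, tests and explanations in this part were chosen only after the results were seen.

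Transcripts of skeletal muscle appeared in 1 library, Thp1 replicate 2, which the report's comparisons did not examine for them. A list of 35 muscle genes had a median of 39.3 CPM there, against 0.147 and 0 CPM in the other Thp1 libraries, and 26 of the 35 genes were at least 10 times above both and at 1 CPM or more. The 35 genes together held 0.615% of the counts. The most abundant were ACTA1 at 1190 CPM, MYH1 at 637, MYH4 at 612, CKM at 565 and TNNC2 at 557 CPM, while DES, at 24 CPM in another Thp1 library, is also expressed by Thp1 itself. Carry-over from another library of the series is argued against, since the highest median of the list in the other 35 libraries was 0.3 CPM, and human muscle RNA is argued against because 7 list genes were under 1 CPM, among them the abundant CA3, MB and MYL2 with no count. Muscle RNA of another animal remains a candidate explanation: MYH4, a fast myosin that human limb muscle hardly uses, held 34% of the counts of 4 myosin heavy chains, and the missing genes could be those whose reads do not match the human genes. No biological explanation was tested, since the design names none, and what brought the RNA into this library stays open.

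Mix1 a, Mix5 c and Mix6 c stood apart from their replicates and shared a trend with transcript length. Genes with longer transcripts were higher in them, with Spearman rho across genes of 0.55, 0.45 and 0.45, a size also reached by T47D replicate 1 (0.5) and Mix2 b (0.49), and the fifth of genes with the shortest transcripts lay at −0.53, −0.25 and −0.2 on the log2 scale, beyond the lowest value of −0.13 in the 31 libraries that did not stand apart. Mitochondrially encoded genes were left out of this trend, and their percentage rose in the same libraries. A loss of all short transcripts was therefore not tested. A loss of short nuclear transcripts could produce the trend. A trend with GC content given length could add to it in Mix1 a (partial rho −0.37) and Mix6 c (−0.18) but not in Mix5 c, where it had the opposite sign (0.16). Another mix of the lines is argued against, because the mitochondrial percentage exceeded the sum of the lines by 2.16 points or more in these libraries and by 0.74 at most in the other mixture libraries.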

How the results depend on the processing

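The alternative without the 5 libraries that stood apart, and every alternative for the counts of genes below every other line, were chosen only after the results were seen, and all others were planned. The counts of genes for each line against the mean of the others, above every other line and among the breast cancer lines, and those of Mix1, Mix2, Mix5 and the F test, stayed within 1.5 times under each alternative. So did the counts below every other line, except that of hMSC, 465, which was 764 with total-count scaling. Each line's share kept a permutation p under 0.05 throughout. The count of Mix3 was 423, 682 with DESeq2 and 958 without the 5 libraries, and that of Mix4 was 530 and 1389 without the 5 libraries. Leaving out 1 replicate at a time gave 202 to 733 for Mix3, 253 to 983 for Mix4 and 770 to 3332 for Mix6 (1884 with all), each lowest without a replicate of the mixture itself, where fewer samples were tested, and each highest without Mix1 a. The genes below all 6 lines, 1 by edgeR and by DESeq2, were 0 with total-count scaling, 0 with a log2 fold change of at least 1 (where those above went from 5 to 2) and 0 to 1 when replicates were left out. The correlation with the linear prediction was 0.988 with a pseudocount of 0.1 against 0.994. Of 390 list tests 154 were called with the preset correlation and 64 with an estimated one, all 64 among the 154. COL1A1 was not called in Mix3 or Mix6 in the fit of all 36 samples (adjusted p = 0.444 and 0.267). COL1A1 in Jurkat, below every other line, ran from −2.59 to 5.13 in log2 when replicates were left out, 5.13 without Thp1 replicate 2, and was at 5.19 without the 5 libraries, both of which leave out the Thp1 library with nearly all COL1A1 counts of that line. HSPA5, ATF4 and NFKB1 in hMSC turned to −0.18, −0.026 and −0.43 with total-count scaling. Of 4990 values for named genes under an alternative 4920 kept direction and call, 65 lost the call and 5 reversed, and of 1476 single shares 79 moved by more than the spread between replicates. Except where a construction is named, the cause was not tested.

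Replicate names did not pair the libraries: correlations of deviations between libraries with the same name ran from −0.04 to 0.05 in the lines and from −0.19 to 0.15 in the mixtures, and 4 and 3 of 18 libraries correlated best with their own name. With the name as a block the counts were 369 for Mix3, 436 for Mix4, 1632 for Mix6 and 9059 for the F test, and MATR3 and H2BC5 in Mix5 were not called (adjusted p = 0.0875 and 0.0698 by edgeR). TPM in place of CPM was not run, since the table used here holds counts. At this depth and spread, 52.5% of simulated changes of 0.5 on the log2 scale were found in the comparison of Mix1.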

Other observations

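Among the results in this part, the sum of the lines against each list and gene, the splits for the counts of genes below every other line, the lists without Mix1 a and the tests of explanations were chosen only after the results were seen.

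Set against the sum of the lines at the estimated shares, the medians of several gene lists departed in the mixtures, though members went both ways. Immediate early genes, which respond within minutes to stimuli, lay above the sum by a median of 0.54 on the log2 scale, in 17 of 18 libraries with 21 of 23 members above, and estrogen response genes by 0.37, in 17 of 18 with 19 of 21 members above. Hypoxia and glycolysis genes (19 of 23 members) lay 0.15 above and luminal genes (21 of 30) 0.11 above, each in 18 of 18 libraries. Interferon response genes lay below the sum by a median of −0.48, with a range of −0.94 to −0.14 over libraries, mesenchymal genes by −0.46 (0.43 with shares from undivided genes) and heat shock genes by −0.16, each below in 18 of 18. The members below were 14 of 16, 29 of 40 and 13 of 15. The interferon list lay lowest in Mix5 (−0.94, −0.78 and −0.9 over its libraries), where the MCF7 share was highest. In Mix1, where that share was lowest, it lay at −0.31, −0.23 and −0.14. Its members furthest below, IFI27, IFI6 and OAS1 (−3.27, −2.21 and −1.8), had their highest pure level in MCF7. STAT1 and BST2, highest in hMSC and T47D, were at −0.35 and −0.47. The medians were set against 10000 random lists of the same size and expression. Those of the immediate early, estrogen, hypoxia and luminal lists were at percentile 100, as was that of the mitochondrially encoded list (0.17). Those of the interferon, mesenchymal and heat shock lists were at percentile 0. Markers used for the shares included 13 mesenchymal, 5 luminal, 4 interferon and 2 estrogen response members. Extreme percentiles were not particular to these lists. The ribosomal protein (median −0.05), basal, myeloid and unfolded protein lists were at 0.26, 0.28, 0.32 and 0.68. The 17q23 and histone lists were at 99.76 and 99.89, and the remaining lists ran from 36.35 to 95.69. Members of the random lists were drawn independently, so a list of genes that vary together reaches such percentiles more easily. With single replicates of the lines as reference the interferon median of a library ran from −1.03 to −0.11, the mesenchymal median from −0.71 to 0.01, the estrogen median from −0.07 to 0.73 and the immediate early median from −0.15 to 0.8.

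Single genes departed by over 1.5 times in the same direction in every mixture library, 10 above the sum and 25 below. They were counted only among genes whose measured and predicted levels averaged at least 5 CPM. The 13079 genes compared were those of at least 2 CPM, so departures of the lower genes were not counted. EGR1, an immediate early transcription factor, was at 116 CPM against 24.1 predicted, SERPINB2 at 14.5 against 1.23 and CTSK, a collagen-degrading protease, at 17.4 against 3.09. INPP5D, an inositol phosphatase of blood cells, was at 58.7 against 17.3 CPM. Several matrix genes lay below, with COL1A1 at 202 against 544 CPM, FN1 at 412 against 981, the elastin gene ELN at 1.91 against 18.9 and the cartilage proteoglycan ACAN at 0.685 against 22.8. With shares from undivided genes COL1A1 and FN1 were at −0.16 and 0.15 on the log2 scale in place of −1.35 and −1.21, while ELN and ACAN stayed below at −1.54 and −2.72. The interferon-induced genes ISG15 and IFI27 were at 17.7 against 65.5 and 0.543 against 12.6 CPM. Of the 25 genes, 7 were on the muscle list, for which Thp1 replicate 2 raised the prediction, and without the 5 libraries ACTA1 was at −0.25 in place of −5.59 and TPM2, which hMSC also expresses, at −0.56 in place of −1.

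An error in the hMSC share alone is argued against, since among 21 genes that come almost only from hMSC 5 lay above and 3 below the median such gene by over 1.5 times in every library, and a share moves all of them by the same factor. Counts against the sum itself depend on the share: of 97 genes used mainly by hMSC 12 lay below and 4 above in every library, 2 and 19 with shares from undivided genes and 1 and 1 with shares from all filtered genes. For the lower matrix genes such an error stays open, because the mesenchymal median was 0.43 with shares from undivided genes and −0.73 with shares from all filtered genes, so even its direction depends on the share. The libraries that stood apart are argued against for the interferon list, whose median was −0.49 without them. Another state of the cells in the mixed pellets, such as recent stimulation or less interferon signalling, may be behind the departures and cannot be told apart from a state peculiar to the pure cultures, since all 6 mixtures share the same line references and the correlation of hMSC departures between mixtures, 0.93 or more, decides nothing.

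Further gene lists were called in the mixtures. In Mix6 the 17q23 list was lower in 13 of 18 cases (camera adjusted p = 4.48e-16, and adjusted p = 0.008 with an estimated correlation) and in Mix4 higher genes included 5 of 16 on the 17q12 list (camera adjusted p = 4.7e-10, and adjusted p = 0.00339 with an estimated correlation). In Mix2 the 20q13 list was higher in 13 of 18 cases (camera adjusted p = 1.03e-07, and adjusted p = 0.00358 with an estimated correlation). Immediate early genes were lower in 21 of 26 cases in Mix1 (camera adjusted p = 1.27e-09, and adjusted p = 0.191 with an estimated correlation), and in 20 without Mix1 a (camera adjusted p = 3.96e-09, and adjusted p = 0.135 with an estimated correlation). Against the sum of the lines Mix1 a stood at −0.14 for this list and its replicates at 0.61 and 0.55.

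Other splits of the libraries were drawn for every count of genes, 100 for each with the real one included. Chance was excluded at a limit of 5 in 100 for each count, since at most 2 of the 100 splits gave as many genes. Most other splits mix groups that differ and gave no gene, so this excludes only a random grouping of the libraries and says nothing of single genes. No other split gave as many genes for the lines against the mean of the others, for which the real and the highest other counts were 12334 and 867 for BT474, 12471 and 3087 for T47D, 12210 and 1271 for MCF7, 12686 and 746 for Thp1, 12490 and 883 for Jurkat and 13074 and 1870 for hMSC. For genes above every other line they were 310 and 0 for BT474, 323 and 106 for T47D, 313 and 0 for MCF7, 397 and 0 for Thp1, 445 and 0 for Jurkat and 1187 and 30 for hMSC. For genes below every other line they were 232 and 0 for BT474, 96 and 0 for MCF7, 923 and 0 for Thp1, 446 and 0 for Jurkat and 465 and 56 for hMSC, and for T47D, where 2 of 100 splits gave as many, 152 and 278. Among the breast cancer lines they were 12167 and 8132 for BT474, 12120 and 8077 for T47D and 12104 and 8113 for MCF7. Among the mixtures they were 7725 and 689 for Mix1, 7931 and 1246 for Mix2, 4717 and 450 for Mix5 and 9566 and 2222 for the F test, with 1 split of 100 as large in each of these cases. For Mix3, Mix4 and Mix6, 2 of 100 splits gave as many genes, with 423 and 1563, 530 and 995, and 1884 and 5533. Splits that called more genes than the real one, for Mix3, Mix4, Mix6 and the genes below every other line in T47D, may reflect a structure of the samples. That structure includes the differences among the groups themselves, and the cause was not tested. For genes above and below all 6 lines the real counts were 5 and 1 and the highest others 0 and 0, but the 1 gene below, PHF23, was not called with total-count scaling (adjusted p = 0.555) or without T47D replicate 3 (adjusted p = 0.507).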
